A study of Petunia x hybrida with 4 samples.

How the data were processed

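Protoplasts of petunia petals were loaded on the 10x Genomics Chromium chip and prepared with a droplet-based 3-prime single-cell kit, per the labels' protocols. Corollas of about 15 flowers went into each wild-type replicate and of about 30 into star and wico. The suspensions were loaded at 345 cells per microlitre for wild type 1, 560 for wild type 2, 480 for star and 590 for wico. The submitters' processing notes name FastQC 0.12.1, Cell Ranger 7.0.1 and Seurat 5.1.0, and the genome build is not given in the sources used here. The values the authors deposited are raw UMI counts per gene and barcode, whole numbers with no normalization, for 31729 gene IDs. Each run listed exactly 4000 barcodes, and how these were separated from empty droplets is not stated. Wild type 2 was deposited as runs A and B and as a joint matrix. In the joint matrix run A held 100% and run B 95.3% of the UMIs of its own file, and the joint matrix was used. The runs were summed and counted as 1 library, and 20 of 5315 genes differed 2-fold between them. No reference genome or table of gene names was used. The second column of the gene tables repeats the ID in every row, with 0 IDs paired with a different name.

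Barcodes with at least 500 UMIs and 300 genes were kept, which removed 0 barcodes from wild type 1, 40 from wild type 2, 32 from star and 296 from wico. Scrublet at an expected rate of 0.04 called 0 doublets in every run, so none was removed. An alternative removed the 4% of barcodes with the highest scores in each run, 785 in all. Organelle genes are not labelled in the files, so no filter on them was applied. Seurat 5.3.0 under R 4.3.3 scaled each cell to 10000 UMIs on a log scale, took 2000 variable genes, integrated the 4 libraries by reciprocal PCA over 30 dimensions and clustered at resolution 0.5. Clusters with 20 or more cells in every library were tested. Clusters of alternative settings were matched to the main ones by the largest number of shared cells. A cluster that several main clusters matched entered the medians once, and a main cluster was followed singly where it gave at least 50% of its match. Star and wico had fewer UMIs per cell than wild type in some clusters. In cluster 11 the median was 3675 and 5641 UMIs in the wild-type libraries, 2002 in star and 1226.5 in wico.

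Counts were summed per library, over all cells or within a cluster, because cells are not replicates. edgeR 4.0.16 (quasi-likelihood test, TMM factors, its default low-count filter, Benjamini-Hochberg adjusted p under 0.05) fitted the 4 libraries in 1 model. Star and wico have 1 library each, so the spread rests on 1 residual degree of freedom from the wild-type pair, and the common dispersion over all cells was 0.139. The labels name the wild-type libraries as biological replicates. The wild-type spread is known from 2 libraries, and star and wico are assumed to share it in each count and adjusted p. The fit was tested on simulated counts with known changes, placed only in genes with a wild-type mean above 20 CPM. For wico over all cells it recovered 15.5% of 4-fold and 97.8% of 16-fold changes, and 4 of its 92 calls were false. For star 3 of 101 calls were false. In cluster 3 the false calls were 10 of 119 in wico and 1 of 107 in star, and in cluster 11 they were 1 of 61 and 2 of 94. In cluster 11, where the counts were lowest, it recovered 81.8% of 16-fold changes in star and 60% in wico. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. CPM values of named genes were computed from the deposited counts with TMM library sizes. Counts of genes without a model, marker sums and distances used plain library totals, with log2(CPM + 1) for the first. A gene with 0 UMIs was set against a floor of 3 UMIs in its library. Intervals and floors cover counting error only. Python 3.11.15 with scanpy 1.11.5 and scipy 1.17.1 did the remaining steps.

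Before the data were examined, the groups, the tests, the cell filter, the clustering, the alternatives and the rule for named genes were fixed. The rule took, for star and for wico over all cells, the 2 IDs with the largest rise and the 2 with the largest fall among genes with adjusted p under 0.05, 20 CPM or more in the higher group and at least 2-fold beyond both wild-type libraries. Among the genes tested, 120 higher and 207 lower genes met the criteria in star, and 210 and 464 in wico. The planned work on PhDEF and related genes, on named gene lists, on cell type markers and on the epidermis against the mesophyll needs gene names, which the files do not pair with the IDs, and was not run. In its place, chosen after the data had been examined, numbered clusters, groups of clusters, marker lists of wild-type clusters and a distance between libraries were used. Groups of clusters came from a tree of the correlation of wild-type profiles divided into 6 groups, after divisions into fewer groups had been looked at. Marker genes had at least 50 CPM in their wild-type cluster, were highest there and lay at least 2-fold above the mean of the other clusters (pseudocount of 5 CPM) in both wild-type libraries, with a mean of 10 CPM or more over the 4 libraries. Lists of 10 or more genes from clusters with 20 or more cells in each wild-type library were tested with camera and fry (limma 3.58.1). Distances were the mean of 20 thinnings of the summed counts to the lowest library, over genes with a mean of 50 CPM or more and a pseudocount of 10 CPM, each divided at random into 2 equal parts so that counting noise cancels. Chance values for the overlap of star and wico came from 30 simulated draws in place of the 100 planned. Alternatives were other size factors, no low-count filter, DESeq2 1.42.0, no cell filter, minima of 1000 and 3000 UMIs, each run of wild type 2 alone, 1 wild-type library left out, resolutions of 0.3 and 1.0, no integration, the removal of high doublet scores, and clustering without the genes that differ between genotypes.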

Results

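The series profiled single protoplasts, plant cells freed of their walls by enzymes, from whole petals (tube and limb) of petunia line R27 at anthesis. According to the series title, the subject is what the petal identity regulator PhDEF does in each cell layer. PhDEF is a B-class MADS-box transcription factor, a class of proteins that specifies petals and stamens. Flowers of 3 genotypes were compared. Wild-type petals gave 2 libraries, which the labels call biological replicates. The star petals, per the labels, carried a mutant phdef epidermis over a wild-type mesophyll, and the wico petals carried the reverse arrangement. Star and wico were represented by 1 library each. Wild type 1 held 22511339 unique molecular identifiers (UMIs, each standing for 1 captured transcript) and wild type 2, sequenced as 2 runs, held 42716997. The star library held 23946211 UMIs and the wico library 19016394. Each run listed exactly 4000 barcodes, and 19632 of the 20000 barcodes passed the cell filter. The median number of UMIs per kept cell was 3270.5 in wild type 1, 2161 in wild type 2, 2329 in star and 1861 in wico. The files list gene IDs alone and do not pair them with names, so PhDEF itself was not checked, clusters carry numbers in place of cell type names, and the epidermis and mesophyll were not assigned.

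The comparison of star with wild type over all cells asked what a mutant epidermis over a wild-type mesophyll changes in the petal. Counts were summed per library, and 274 genes were higher and 437 lower in star, of 17889 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Peaxi162Scf00030g00022 stood at 55.9 CPM (UMI counts scaled to the TMM library size) in star against 2.58 and 2.71 in the wild-type libraries, a log2 fold change of 4.40 ± 0.63 (SE, edgeR adjusted p = 5.15e-09). Peaxi162Scf00016g00332 stood at 63.5 CPM in star against 3.6 and 3.16, a log2 fold change of 4.23 ± 0.63 (edgeR adjusted p = 2.27e-08). In the other direction, Peaxi162Scf00595g00212 had 4 UMIs in star against 1273 and 2014 in wild type, a log2 fold change of -8.24 ± 1.04 (edgeR adjusted p = 1.31e-11). Peaxi162Scf00040g00425 had 0 UMIs in star, 838 in wild type 1 and 458 in wild type 2. Set against a floor of 3 UMIs in the star library, it was at least 189-fold lower than the wild-type mean and 89.3-fold lower than the lower wild-type library (edgeR adjusted p = 1.31e-11). Within clusters, Peaxi162Scf00030g00022 was called in star in 5 of the 8 clusters that tested it, Peaxi162Scf00016g00332 in 2 of 6 and Peaxi162Scf00595g00212 in 2 of 4, and Peaxi162Scf00040g00425 was tested in 0. The 2 IDs that fell were transcribed in a narrow set of wild-type cells. Clusters 4, 9 and 11 held 99.3% of the wild-type UMIs of Peaxi162Scf00040g00425 and 94.0% of those of Peaxi162Scf00595g00212. These clusters held 5.12% of the star cells against 36.6% and 27.0% of the wild-type cells. Fewer such cells would lower both IDs over all cells, but their part in each fall was not measured. Peaxi162Scf00595g00212 fell further than the share of cells, to 0.164 CPM in star against 53.9 and 48.3 CPM in wild type. It was also called lower within 2 clusters. That shows more than fewer cells only if the star cells there were of the same kind as the wild-type cells. This was not tested for the ID, so a change within clusters and fewer cells both stay open. For Peaxi162Scf00040g00425, tested in 0 clusters, a change within clusters cannot be told apart from fewer cells. Star entered with 1 library, so the test assumes that it varies like the 2 wild-type libraries, whose single residual degree of freedom sets the spread. In simulated counts for this comparison, the test recovered 0% of 2-fold, 19% of 4-fold, 79.6% of 8-fold and 97.8% of 16-fold changes. The changed genes were drawn from those above 20 CPM in wild type, so recovery at lower counts was not measured.

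The comparison of wico with wild type asked the same of a mutant mesophyll under a wild-type epidermis. In wico, 460 genes were higher and 1094 lower than in wild type by the same test. Peaxi162Scf00948g00225 rose to 752 CPM from 14.2 and 13 CPM in the wild-type libraries, a log2 fold change of 5.79 ± 0.65 (edgeR adjusted p = 4.28e-15), and stood at 216 CPM in star. In wild type, 88.7% of its UMIs lay in clusters 2, 5, 6, 7 and 10, and in wico 92.8% did. Peaxi162Scf00030g00022 rose in wico too, to 105 CPM, a log2 fold change of 5.31 ± 0.65 (edgeR adjusted p = 9.2e-13). Peaxi162Scf00297g00815 had 9 UMIs in the whole wico library, against 3463 and 33744 in wild type and 3298 in star. Its log2 fold change in wico was -9.87 ± 1.06 (edgeR adjusted p = 2.29e-16). Peaxi162Scf00297g00816 had 24 UMIs in wico against 1663 and 22035 in wild type and 4825 in star, a log2 fold change of -7.79 ± 0.96 (edgeR adjusted p = 3.16e-12). Both were called lower in wico in 9 of 10 tested clusters. Their wild-type libraries stood far apart, at 147 and 808 CPM for the first ID and at 70.4 and 528 CPM for the second. Without wild type 2 their log2 fold changes were -7.984 and -5.632. As for star, the single wico library was assumed to vary like the wild-type libraries.

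**Figure D1:**
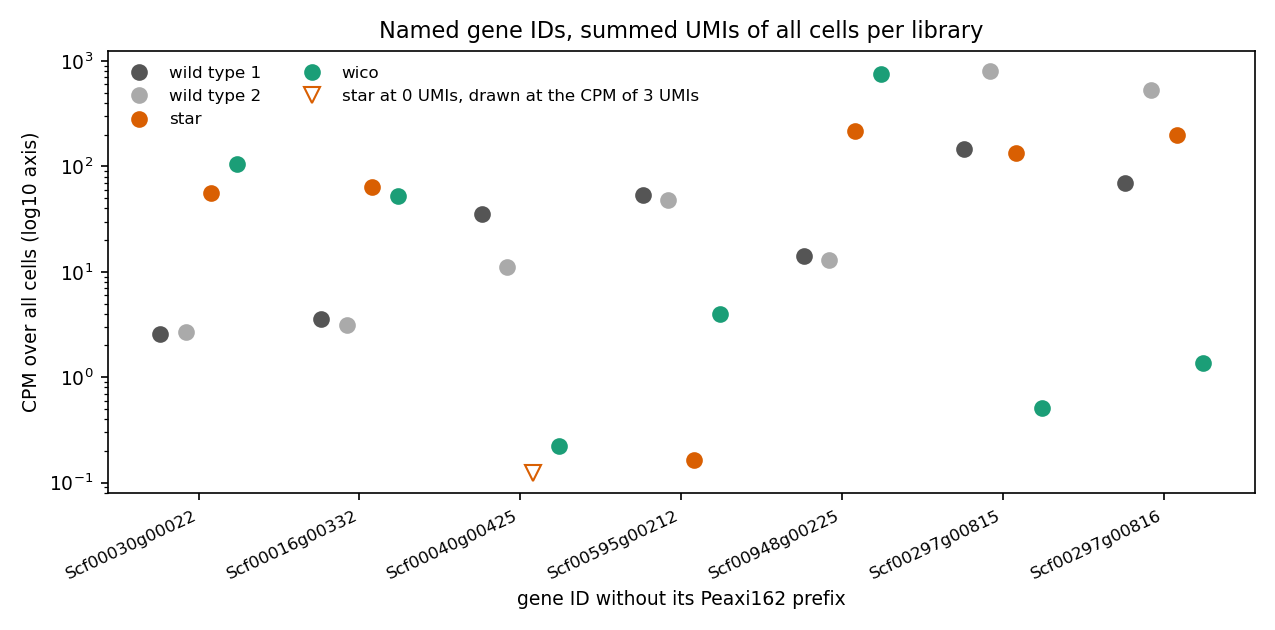
CPM over all cells on a log10 axis for the gene IDs named by the rule, 1 point per library. The open triangle marks the ID with 0 UMIs in star, drawn at the CPM of 3 UMIs. Peaxi162Scf00948g00225 stood at 752 CPM in wico and 216 CPM in star against 14.2 and 13 CPM in the wild-type libraries.

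The chimeras were also compared with each other, 1 library against 1. Set directly against wico, star had 29 genes higher and 10 lower (edgeR, adjusted p under 0.05, with the spread of the wild-type pair). DESeq2 called 16 such genes in place of 39, and 25 were called with run B alone standing for wild type 2. The share of changes that this test recovers was not simulated, so the counts do not show that few genes differ. Of the 274 genes higher in star, 177 were also called higher in wico, where independent lists would share 7, and 2 were called lower. Of the 437 genes lower in star, 356 were also called lower in wico, where independent lists would share 26.7. Unchanged libraries simulated against the same wild-type pair had 0.07 calls each on average over 30 draws and shared 0.03, so they do not measure the sharing between lists of this length. Across the 17889 genes, which are not independent replicates, the log2 fold changes of star and wico correlated with Pearson's r of 0.773. The simulated libraries gave a mean r of 0.322. The covariance was 1.004 against 0.164 in the simulation, a difference of 0.84. With wild type 1 serving star and wild type 2 serving wico the covariance was 0.774, and with the wild types exchanged it was 0.872, where the simulation gave 0.001 and 0. The wild-type libraries were too few to be split into parts of 2 libraries each, so part of the overlap of calls may come from the shared controls. Star and wico also shared a shift in the mix of cells. Clusters 4 and 9 together held 2.02% of star and 8.32% of wico against 34.1% and 21.8% of the wild types. The overlap was not measured within clusters, so a shared mix and a shared response of genes cannot be told apart here.

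Counted without a model, 342 genes stood at least 2-fold above both wild-type libraries in star and 651 stood at least 2-fold below both, among 6356 genes with 20 CPM or more in any library. In wico, 353 genes stood above both and 967 below both. The wild-type libraries differed from each other 2-fold or more in 1087 of the same genes. At a 4-fold threshold, star kept 216 genes and wico 419, and the wild-type pair differed in 79. With 1 wild-type library alone as the reference, the star count was 1926 without wild type 1 and 1727 without wild type 2, and the wico count was 2243 and 1940.

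Clustering of the integrated cells gave 14 clusters. Cells of clusters 4 and 9 were scarce in both chimeras. Together these clusters held 34.1% of the cells of wild type 1 (95% exact binomial interval 32.6 to 35.5) and 21.8% of wild type 2 (20.9 to 22.7), against 2.02% of star (1.60 to 2.50) and 8.32% of wico (7.45 to 9.25). When the cells were clustered again without 2483 genes that differed between genotypes, the matching clusters held 31.95% and 20.6% of the wild-type libraries, 2.72% of star and 8.396% of wico. Cluster 8 was larger in the chimeras, with 7.36% of star and 7.40% of wico against 2.95% and 5.43% of the wild types, and without those genes the matching cluster held 6.83% and 6.45% against 2.90% and 5.08%. Clusters 2, 5, 6, 7 and 10 together held 63.9% of star and 63.3% of wico against 40.4% and 29.3% of the wild types. Without those genes their matching clusters held 66.6% and 59.6% against 43.9% and 51.3%, so the distance from wild type 2 was smaller there. At resolution 0.3, where the matching clusters took in clusters 1, 4 and 11, they held 77.1% of star and 72.9% of wico against 69.9% and 73.8%, so wico no longer stood above both. The intervals cover counting error only, and no test of shares was made. The shares refer to the 4000 barcodes listed per run. How these were chosen is not stated, and the lowest held 1749 UMIs in wild type 1, 672 in wild type 2, 948 in star and 670 in wico.

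**Figure D2:**
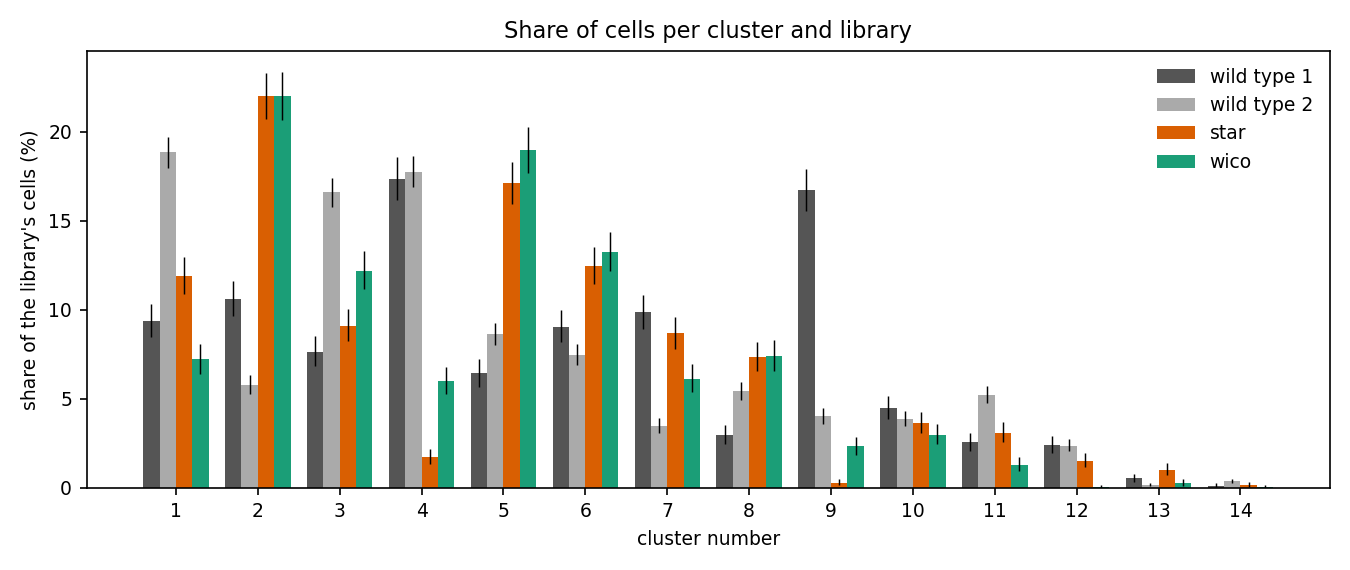
Share of each library's kept cells in each of the 14 clusters, in percent, with 95% exact binomial intervals that cover counting error only. Cluster 4 held 17.4% and 17.8% of the wild-type cells against 1.74% of star and 5.99% of wico, and the wild-type libraries themselves differed in cluster 9, at 16.7% and 4.02%.

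Marker genes of the wild-type clusters were summed over each library, which places no star or wico cell in a cluster. The lists were drawn from wild-type cells clustered alone, after the data had been examined. The same wild-type libraries then served as the controls, and this reuse favours lower values in star and wico. The 184 markers of the cluster that matched cluster 9 summed to 18361 CPM in star and 13535 CPM in wico, against 43230 and 38963 CPM in the wild-type libraries. Of these markers 61 fell and 0 rose in star, and 79 fell and 0 rose in wico. Adjusted over the list alone, 90 fell in star, and 105 fell and 1 rose in wico. Of the 241 markers of the cluster that matched cluster 4, 34 fell and 0 rose in star, and 46 fell and 0 rose in wico. Their summed CPM was 0.519 of the wild-type mean in star and 0.526 in wico. Against the wild-type means, the sums fell less than the shares of cells did. Other cells can add to these sums, since a marker needed only 2-fold over the mean of the other clusters. The sums expected from the shares alone were not computed. Star held the lower share of both clusters, but the lower sum only for cluster 4, by a small margin. Of the 107 markers of cluster 12, 16 fell in star and 34 in wico, and 0 rose in either, with a summed CPM of 0.672 of the wild-type mean in star and 0.701 in wico. Of the 93 markers of the cluster that matched cluster 6 most often, 11 rose in star and 23 in wico, and 0 fell. That wild-type cluster was mixed, with 35.7% of its cells in cluster 6. Of 38 markers matched to cluster 1, 3 fell in star and 15 in wico. Of 179 markers matched to cluster 8, 10 rose and 2 fell in star, and 14 rose and 12 fell in wico. Of 62 markers matched to cluster 7, 4 fell in star, and 1 rose and 10 fell in wico, and of 15 markers matched to cluster 3, 2 rose and 5 fell in wico and 0 passed in star. For the cluster 7 list in both chimeras and the cluster 3 list in wico, the median log2 fold change lay below 0 while the summed CPM lay above the wild-type mean. Camera with a preset correlation of 0.01 placed the lists of clusters 1, 4, 6, 9 and 12 beyond the other genes in both chimeras, with adjusted p from 9.92e-36 to 0.000168, and the list of cluster 8 in star (adjusted p = 0.00412). With an estimated correlation the adjusted p of these lists by camera ran from 0.422 to 0.641 in star and from 0.462 to 0.592 in wico, and no list call held. That version rests on the 1 residual degree of freedom, so it could hardly pass a list at any correlation. The estimated correlation of the cluster 9 list was 0.012, near the preset 0.01. It was higher for the lists of clusters 1 (0.795), 12 (0.753), 6 (0.132), 8 (0.111) and 4 (0.06). For those lists the preset version assumes less correlation than was estimated, so its adjusted p may be too small. The preset version takes its spread from genes and not from libraries. By fry, which rests on the same degree of freedom, the adjusted p of all 8 lists lay at 0.319 or above.

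**Figure D3:**
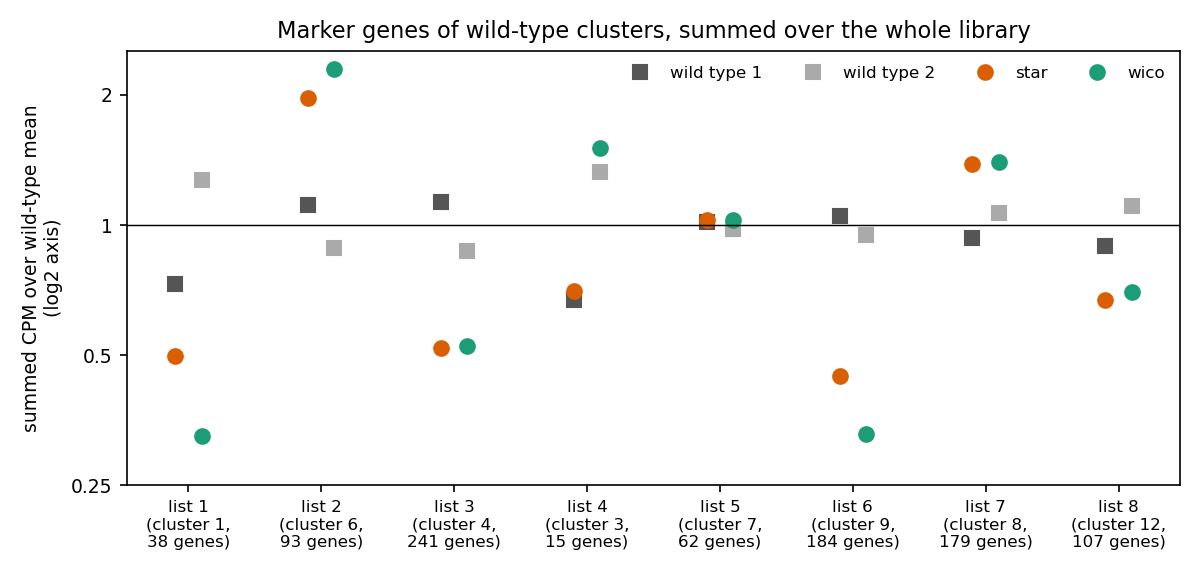
Summed CPM of the markers of each wild-type cluster over the whole library, divided by the mean of the 2 wild-type libraries, on a log2 axis with 1 point per library. List 6, which matched cluster 9, lay at 0.447 in star and 0.329 in wico, and list 2, which matched cluster 6 most often, at 1.97 and 2.30.

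The response was then counted cluster by cluster, in the 10 clusters with 20 or more cells in every library. Wico had more calls than star in 7 of the 10. In cluster 8, 515 genes differed from wild type in wico and 67 in star. In cluster 1 the counts were 273 in wico and 31 in star, and in cluster 3 they were 379 and 33. Cluster 11 went the other way, with 286 genes in star and 32 in wico, as did the count in cluster 7 with 72 and 23. Cluster 11 held 48 wico cells and 123 star cells. In simulated counts for it, the test recovered 45.3% of 8-fold changes in wico and 69.8% in star, so its counts were not at equal detection. Set directly against wico by edgeR, star differed in 51 genes in cluster 8, 38 in cluster 1, 16 in cluster 3 and 25 in cluster 11. In cluster 7 it differed in 0, so the counts there do not show a difference between the chimeras. Cluster 4 had few calls, 9 in star and 3 in wico, and its order was not stable, with 36 and 55 under DESeq2's size factors and 30 and 61 at resolution 1.0. Counts in other clusters depended on the settings. DESeq2 gave 8 in star and 243 in wico in cluster 8, 1 and 88 in cluster 1, 18 and 219 in cluster 3, and 58 and 3 in cluster 11. Cluster 11 had 139 and 8 with no low-count filter and 120 and 6 with 1000 or more UMIs. In cluster 1, star had 4 calls with run B alone and 10 without the highest doublet scores. Over the 10 clusters the median was 32 calls in star and 233.5 in wico, again with each lone library assumed to vary like the wild types. Of the genes lower over all cells, 110 of 437 in star and 470 of 1094 in wico were also called lower in at least 1 cluster. For the genes higher over all cells these counts were 120 of 274 in star and 240 of 460 in wico. Without integration of the libraries, the median over the 7 distinct matching clusters was 45 calls in star and 28 in wico. Wico still had more calls in 4 of these clusters and star in 2, with 835 and 482 calls summed over them. Cluster 1 had 87 calls in star and 49 in wico, and its matching cluster held only 1.22% of the wico cells. Cluster 8 kept its order without integration, with 60 calls in star and 491 in wico. The closest match of cluster 7, of which it gave 47.6% of the cells, had 1 call in star and 24 in wico. Cluster 11 shared its matching cluster with cluster 4, so it could not be followed. Nor could cluster 3, whose matching cluster held 0.162% of the wico cells, below the minimum of 20 cells.

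**Figure D4:**
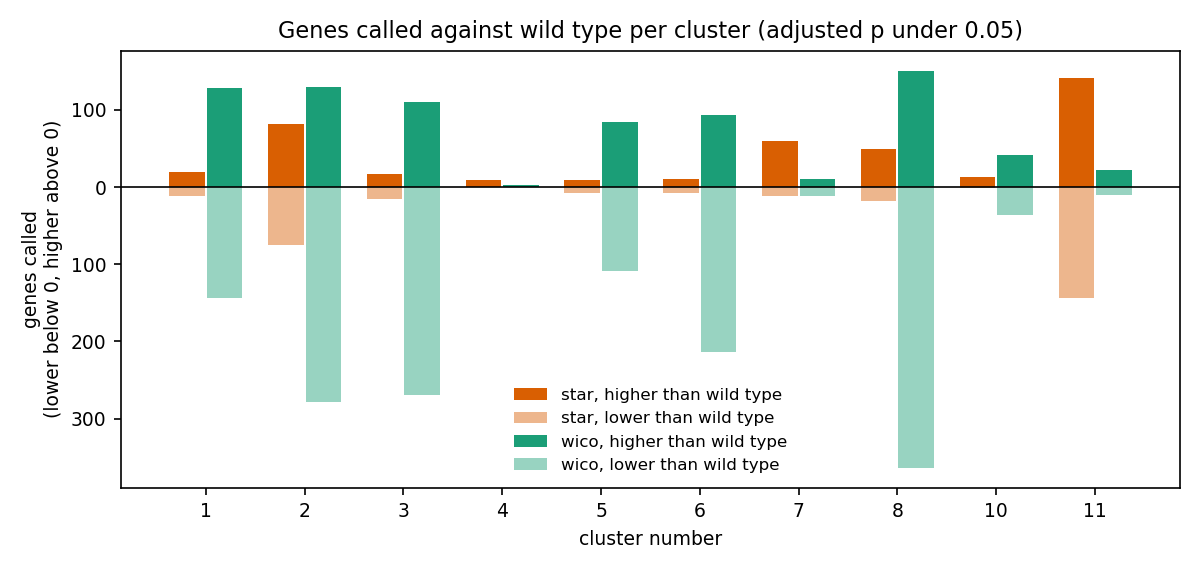
Number of genes called against wild type in each tested cluster (edgeR, adjusted p under 0.05), with genes higher in the chimera above 0 and genes lower below 0. Wico exceeded star in cluster 8, with 515 calls against 67, and star exceeded wico in cluster 11, with 286 against 32.

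A call in one cluster and not in another does not show a difference, so the difference was tested between 2 groups of clusters. Clusters 4, 9 and 11 resembled each other in wild-type cells, as did clusters 1, 3 and 12, and the groups were chosen after the data had been examined. Their boundary was not sharp, since the lowest correlation inside the group of clusters 4, 9 and 11 was 0.834 and the highest with a cluster outside it was 0.891. With the library as a block, the star response differed between the groups for 0 of 13883 genes by edgeR at adjusted p under 0.05, with 1389 genes at an unadjusted p under that value. The wico response differed for 15 genes, 13 of them with the more positive log2 fold change in clusters 4, 9 and 11. A smaller fall there also counts as more positive, so this does not show a stronger response in that group. The difference between the star and the wico responses passed for 0 genes, with 2085 at an unadjusted p under 0.05. The groups held different cells in each library. Of the cells in clusters 4, 9 and 11, cluster 11 gave 123 of 203 in star and 48 of 356 in wico, against 102 of 1464 and 416 of 2149 in the wild types, and cluster 12 gave 1 wico cell. The group response therefore mixes change within clusters with shifts between them. These counts depended on the cells used. Among cells with 1000 or more UMIs they were 29, 191 and 227, and among cells with 3000 or more UMIs 13, 271 and 215. The direction in wico was less one-sided there, with 117 of 191 and 182 of 271 more positive in clusters 4, 9 and 11.

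The size of the departure from wild type was measured as the root mean square log2 difference over genes at equal UMIs, with counting noise removed. Over all cells the wild-type libraries lay 0.654 apart, star lay 0.933 from wild type on average and wico 1.07, and star and wico lay 0.497 apart. In cluster 1 star lay 0.611 from wild type, near the 0.601 between the wild-type libraries, and wico lay 0.926. In cluster 3 star lay at 0.687 and wico at 0.979, with the wild types 0.66 apart. In cluster 8 star lay at 0.731 and wico at 1.01, with the wild types 0.704 apart. In cluster 11 star lay at 1.05 and wico at 0.887, with the wild types 0.692 apart. These distances carry no test, since each chimera has 1 library. Without integration, 9.4% of the wico cells of cluster 1 and 1.1% of those of cluster 3 fell with the wild-type cells of the same cluster, as did 36.6% of the star cells and 60.4% of the wico cells of cluster 11, and 79.7% and 32.4% of the star cells of clusters 1 and 3. In cluster 8, 95.6% of the wico cells and 93.8% of the star cells did.

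**Figure D5:**
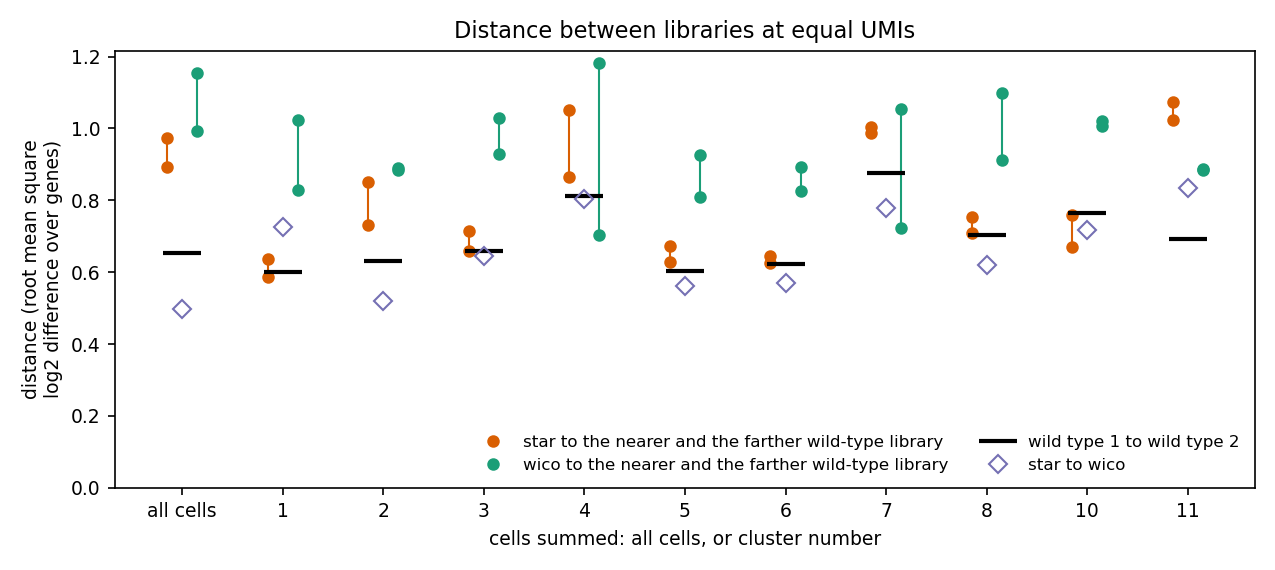
Distance between libraries (root mean square log2 difference over genes at equal UMIs, counting noise removed) over all cells and per tested cluster. Filled points join each chimera to the nearer and the farther wild-type library, black bars give the wild-type pair and open diamonds give star to wico. Over all cells star and wico lay 0.497 apart, below the 0.654 of the wild-type pair.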

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

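The result below comes from groups of clusters that were chosen after the data had been examined, in place of the planned test between named cell layers. The wico response differed between clusters 4, 9 and 11 and clusters 1, 3 and 12 for 15 of 13883 genes (edgeR, library as a block, adjusted p under 0.05), which is a difference between groups of cells under the same contrast. Of these, 13 had the more positive log2 fold change in clusters 4, 9 and 11, which can be a smaller fall. The count was 29 with DESeq2's size factors and 675 with no low-count filter, and 21 and 401 of these were more positive in clusters 4, 9 and 11. It rests on the single wico library, which had 356 cells in clusters 4, 9 and 11, with a median of 1274 UMIs, against 1464 and 2149 cells in the wild-type libraries. Cluster 9 gave 86 of the 356 wico cells, 668 of 1464 in wild type 1 and 320 of 2149 in wild type 2, so the response mixes change within clusters with a shift between them.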

How the results depend on the processing

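The alternatives with 3000 or more UMIs, with the highest doublet scores removed, with the clustering that left out changed genes, and all those for groups of clusters were chosen after the data had been examined. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Keeping called doublets would leave the data as they are, since 0 were called. Leaving out a wild-type library leaves no residual degree of freedom, so those settings gave values without a test. Gene lists, PhDEF and named layers have no alternatives, since they were not run. Over all cells, star called 523 to 1040 genes and wico 1139 to 1942 over the 9 alternatives, within 1.5 times the main counts of 711 and 1554. Star against wico fell from 39 genes to 16 with DESeq2 and 25 with run B alone.

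Per cluster, the median count of 32 calls in star became 13 with DESeq2, 56.5 with 1000 or more UMIs, 83 with 3000 or more UMIs and 60 at resolution 0.3. The median of 233.5 in wico became 132 with no low-count filter, 89.5 with DESeq2, 153.5 with run B alone, 450.5 with 3000 or more UMIs, 435 at resolution 0.3 and 28 without integration. Of 182 counts for single clusters under these settings, 78 moved by more than 1.5 times. The causes were not tested.

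Genes beyond both wild-type libraries numbered 993 in star and 1320 in wico. A 4-fold threshold gave 216 and 419, a pseudocount of 10 CPM gave 651 in star, and a minimum of 50 CPM gave 852 in wico, with fewer genes passing by construction. With 1 wild-type library left out the counts ran from 1727 to 1926 in star and from 1940 to 2243 in wico.

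Clusters 4 and 9 together held 2.02% of star and 8.32% of wico. These shares became 14.0% and 16.0% at resolution 0.3, 1.35% and 5.93% with 1000 or more UMIs, and 12.8% and 9.93% with 3000 or more UMIs. Wico fell to 3.65% without integration, and star stood at 2.72% without the changed genes. At resolution 0.3 and at 3000 UMIs the matched cluster had merged with cluster 7, which gave 62.8% and 87.9% of the star cells in it. The wild-type shares at those settings were 46.7% and 30.8%, and 45.9% and 18.9%. In each setting both chimeras stayed below both wild-type libraries, with the narrowest gap outside those settings at resolution 1.0, where the wild types held 28.2% and 11.1%, star 1.64% and wico 7.69%.

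The correlation of star and wico fold changes was 0.717 with no low-count filter against 0.773. The response by cluster group, 0 genes in star and 15 in wico, became 29 and 191 with 1000 or more UMIs, 13 and 271 with 3000 or more UMIs, and 275 and 675 with no low-count filter. DESeq2's size factors gave 29 in wico. The causes were not tested. Of 88 alternative fold changes of the named IDs, 80 stayed on their side of the threshold or within the spread between the wild types, 8 moved by more, and 0 changed direction. Depth limits the small clusters most, since cluster 11 summed to 81773 UMIs in the shallowest library.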

Other observations

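The tests of a different mix of cells, of few UMIs, of changed genes, of unchanged marker expression and of the placement of wico cells were chosen after their results had been seen. In the wico library 2 genes, Peaxi162Scf00297g00815 and Peaxi162Scf00297g00816, were called lower than wild type in 9 of 10 tested clusters, with 9 and 24 UMIs left in the library. Of 4156 genes with 20 CPM or more in each of the other libraries, these 2 lay 16-fold or more below the lowest of them. Such genes numbered 0 in wild type 1, wild type 2 and star, and no library had a gene 16-fold above the highest of the others. The 2 IDs carry consecutive numbers. Whether they share reads was not tested, nor was a difference of the wico line at these genes that is separate from the mutant layer.

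Cluster 12 was near absence in wico, with 1 of 3704 cells (0.0270%, exact interval 0.001 to 0.15), against 2.40% and 2.37% in the wild-type libraries and 1.51% in star. Without integration the matching cluster again held 1 wico cell. Clustered without the changed genes, its cells joined those of cluster 3, so its size there cannot be given. Its 107 markers kept a summed CPM of 0.701 of the wild-type mean in wico, near the 0.672 of star. A marker needed only 2-fold over the mean of the other clusters, so other cells can add to this sum. The sum expected without the cluster was not computed, so it cannot be set against the cell count.

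Clusters 4 and 9 together held a smaller share of the cells in star and wico than in either wild-type library. Barcodes with few UMIs do not account for it. Among cells with 3000 or more UMIs the shares were 0.850% in star and 3.45% in wico against 37.7% and 25.9% in the wild types. Clustering on the 2483 genes that differed over all cells does not either, with 8.396% as the higher chimera share once these genes were left out. Genes that changed within clusters alone stayed in the clustering, so their part is not settled. Cells with unchanged marker expression in other clusters would have kept the summed markers in the wild-type range. The highest ratio to the lower wild-type library was 0.603, which argues against such cells as the whole cause. Choosing the markers in these wild-type libraries favours a low ratio, however. The sums stayed at 0.447 and 0.519 of the wild-type mean in star, where the share of cells fell further. Other cells can add to these sums, so this gap does not show cells with unchanged marker expression. As a part of the loss such cells stay open. A lower recovery of these protoplasts from chimeric petals, and a change of expression that takes the cells out of these clusters, also stay open and were not tested.

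Star and wico lay closer to each other over all cells than the wild-type libraries did. Distances were taken at equal UMIs. The margin was 0.112 with the clusters weighted equally. Within clusters star and wico were closer in 8 of 10, although by less than the spread of the thinnings in cluster 4 (0.804 against 0.811), but farther apart in cluster 1 (0.727 against 0.601 for the wild types) and cluster 11 (0.833 against 0.692), so a different mix of cells cannot be told apart. Preparation also remains: about 30 flowers went into each chimera against 15 for wild type, and no batch is labelled, so preparation and genotype cannot be told apart. A shared effect of a mutant layer, whichever layer it is, is a candidate explanation that these libraries leave untested.

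Wico lay farther from wild type than star in clusters 1 and 3, and star farther than wico in cluster 11. Wico was also the farther one in clusters 2, 5, 6, 8 and 10, and in cluster 4 they were level (star 0.958, wico 0.943). In cluster 7 star was farther on average, but wico lay farther from wild type 2 (1.054 against 1.005). In clusters 1 and 3 the smaller margin was 0.291 among cells with 3000 or more UMIs, which argues against free RNA in the droplets. In cluster 11 the margin was -0.017 among cells with 3000 or more UMIs, but only 5 wico cells were left, so free RNA cannot be told apart there. Placement by the integration stays a candidate explanation for both, since at most 9.4% of the wico cells of clusters 1 and 3, and 36.6% of the star cells of cluster 11, fell with their wild-type cells without integration. A large response in those cells would separate them too. In each of these 3 clusters the other chimera had the higher share, with 79.7% and 32.4% for star and 60.4% for wico. In cluster 8, outside this pattern, 95.6% of the wico cells fell with the wild-type cells and wico still lay 0.275 farther than star. The mutant layer named in the labels may give such a split, but 0 gene IDs are paired with a name, so the layers of these clusters are not known and it cannot be told apart from the rest.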
